A study of Homo sapiens with 16 samples.

How the data were processed

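RNA of 2 human pancreatic ductal adenocarcinoma lines, BxPC3 and PANC-1, was isolated with a column kit and sequenced after poly-A enrichment, per the labels' protocols. The 16 libraries fall into 4 groups of 4: each line as control and with gemcitabine. Groups and replicate numbers were taken from the sample titles.

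The authors deposited 1 table per line, with FPKM values per gene and library, per the labels and the file headers. Gene length in bases, the other unit used, was deposited in the same tables. CASAVA and HISAT2 are named, without versions, per the submitters' processing notes. The program that counted reads and whether it used strand are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. The notes name the mouse build mm10, yet all 58735 gene identifiers in the deposited tables are human, and 58724 of them have the start and end of the GENCODE 29 annotation on GRCh38, so coordinates are given as GRCh38. Genes were named by the symbols of the tables, of which 1568 occur more than once; list members with such a symbol were left out. The entry for HNRNPA1 in the list of gemcitabine handling was matched to HNRNPA1L2, a different gene, which is counted among the members of that list.

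FPKM multiplied by gene length was a whole multiple of 1 step per library for 100.0% of values, within a tolerance of 0.02 reads, which gives the reads per gene. The listed reads were 0.963 to 1.05 times the library size that the step implies, so that size was not the read total. The deposited values may thus already hold a scaling factor between libraries, which median-ratio scaling may partly repeat. Depth was 28074125 to 37777222 reads in listed genes in BxPC3 controls, 29975612 to 34305420 with gemcitabine, 23007302 to 24913994 in PANC-1 controls and 22152034 to 31642808 with gemcitabine. The floor of 3 reads covers counting error only, since PCR copies are not independent molecules. No pair of libraries of a group differed by as little as counting noise, with chi-square per degree of freedom of at least 2.074.

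Each line was tested alone with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust) on log2(FPKM + 1), over genes with FPKM of at least 1 in at least 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between lines was the interaction over all 16 libraries. Folds are ratios of mean FPKM. Overlap of calls was tested with Fisher's exact test, 2-sided, in R. Tables were read with pandas 2.3.3, libraries of a group were compared by chi-square with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Of 40 gene lists, those with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per line, the 10 largest rises and falls among protein-coding genes past the threshold whose groups did not overlap, up to 4 members with the smallest p of each described list, and any gene of gemcitabine handling. It also took the 8 genes with the smallest p in each direction for the difference, the 6 largest shared changes in each direction, here also among protein-coding genes, a limit that the rule gave for single lines only, and SMAD4 and CDKN2A as label checks. Some genes that the rule took, or that lists hold, are not reported here. The list of mRNAs with a 5' terminal oligopyrimidine tract was written after the fall of ribosomal protein genes was seen and before any value of its own members was.

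Alternatives were a pseudocount of 0.1, no filter, median-ratio and TPM scaling, limma without trend and robust, protein-coding genes only, the replicate number as a block, an absolute log2 change of 1 and each library left out with the tested genes held fixed. Added after the data were seen were limma-voom on the recovered reads and the removal of each library's GC trend, a spline on the GC content of the longest GENCODE transcript. The procedure was tested on simulated data with 200 genes changed per comparison. In BxPC3 it recovered 36.2% of genes changed 1.25-fold, 83.7% at 1.5-fold, 93.5% at 2-fold and 97.8% at 4-fold, with 9 false calls among 11913 unchanged genes. In PANC-1 the shares were 14.0%, 62.5%, 94.0% and 100%, with 17 false calls among 12252, and for the difference 4.00%, 40.0%, 85.7% and 98.0%, with 2 among 13893. Camera called 2 of 2 changed lists at 1.5-fold and no other list in each comparison. The noise was drawn independently for each gene, so these counts do not cover lists of correlated genes or a library with a GC trend. The 200 changed genes were also far fewer than the 8964 of 12215 called in BxPC3. The Benjamini-Hochberg cut depends on this share, so the recovered shares and false calls need not hold for the data. For the difference only PANC-1 was given changes, so false differences from equal folds at unequal levels could not arise.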

Results

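Poly-A-enriched RNA was sequenced from 2 human pancreatic ductal adenocarcinoma cell lines, BxPC3 and PANC-1. Each line was sequenced as untreated control cells and after treatment with gemcitabine, a deoxycytidine analogue that blocks DNA synthesis after phosphorylation in the cell, with 4 libraries in each of the 4 groups. The labels give neither dose nor time, and nothing in them says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The 16 libraries held 22152034 to 37777222 reads in the listed genes, recovered from the FPKM values (fragments per kilobase of transcript, scaled by a factor for each library). A count of 3 reads on a transcript of 1 kb corresponded to 0.0803 to 0.138 FPKM. Levels below are mean FPKM ± SD over 4 libraries, and log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low levels.

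Genes that these lines are known to lack served as a check of the labels. SMAD4, a transducer of TGF-beta signals, had no read in the 8 BxPC3 libraries and stood at 3.84 ± 0.193 FPKM in control and 3.68 ± 0.437 FPKM with gemcitabine in PANC-1. CDKN2A, which encodes the cell cycle inhibitor p16, had no read in any of the 16 libraries. The first principal component parted control from gemcitabine libraries in each line, with 89.3% of the variance in BxPC3 and 70.2% in PANC-1. In PANC-1 the second component, with 20.4%, set gemcitabine replicate 1 apart from the other 7 libraries. That library was higher than the other 3 of its group for GC-rich transcripts and lower for GC-poor ones: the median deviation was 0.45 (log2) over the genes in the top quartile of GC content and -0.42 over those in the bottom quartile. At least 99.988% of the reads of ribosomal RNA genes were mitochondrial in every library.

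**Figure D1:**
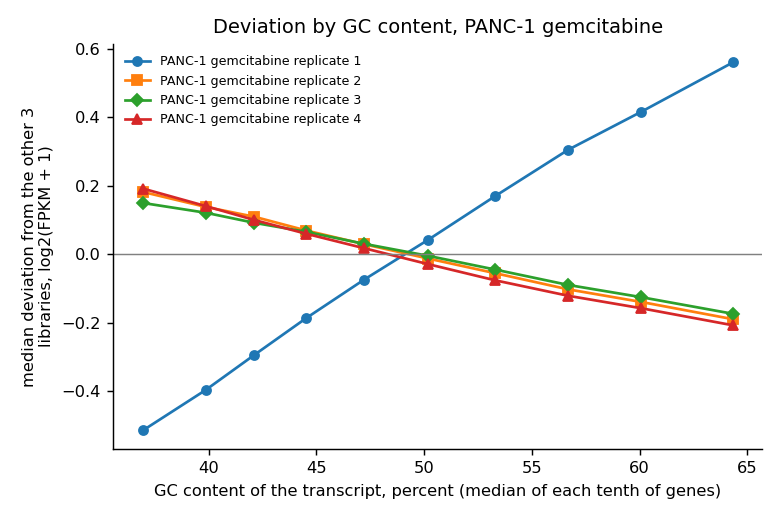
Median deviation of each PANC-1 gemcitabine library from the mean of the other 3, in log2(FPKM + 1), over deciles of the genes by the GC content of their longest transcript (percent, x axis). Replicate 1 runs from -0.51 in the lowest decile to 0.56 in the highest, and the other lines slope the opposite way because replicate 1 is part of the mean each is set against.

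The first comparison asked how gemcitabine changed gene expression in BxPC3. Interferon-stimulated genes, cell cycle genes and secreted inflammatory factors rose, and cytosolic ribosomal protein genes fell. With an estimated correlation the list calls held for interferon-stimulated genes (camera adjusted p = 0.00764) and for genes of G2 and mitosis (adjusted p = 0.00764). They were lost for G1/S genes (adjusted p = 0.0735), secreted factors (adjusted p = 0.208) and ribosomal proteins (adjusted p = 0.400). IFI6, an interferon-induced mitochondrial protein, rose 19.6-fold (from 24.0 ± 2.21 to 471 ± 44.4 FPKM), and IFI27 rose 10.1-fold. The neutrophil chemokines CXCL5 and PPBP rose 17.7-fold and 49.8-fold, and the protease inhibitor SERPINB2 rose 18.9-fold. Ceruloplasmin, encoded by CP, fell from 38.2 ± 2.54 to 1.41 ± 0.141 FPKM, and TXNIP, an inhibitor of thioredoxin, fell from 784 ± 14.5 to 77.4 ± 0.619 FPKM. Of 12215 genes tested with limma, 4556 were higher and 4408 lower with gemcitabine at an adjusted p under 0.05, and 538 and 491 of them also passed an absolute log2 change of 1. In 67.5% of the tested genes the 4 gemcitabine libraries all lay above or all below the 4 controls, where chance gives 2.86%.

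Small proline-rich proteins of squamous epithelia stood among the highest rises: SPRR2E rose 43.4-fold (from 2.59 ± 0.545 to 112 ± 10.1 FPKM) and SPRR2A 12.1-fold. These genes lie close together (chromosome 1, 153093135 to 153106184, and chromosome 1, 153056113 to 153057537, GRCh38) and are near-identical copies, so the division of reads among them is uncertain. The list of squamous differentiation genes as a whole went both ways, with 7 of 18 tested members higher and 7 lower (camera adjusted p = 0.942). Among the largest falls were the stress-induced chromatin protein NUPR1 (from 33.1 ± 2.60 to 1.73 ± 0.165 FPKM), the secreted phosphoprotein SPP1 (from 79.6 ± 5.31 to 7.52 ± 0.711 FPKM), the cytokine IL33 (from 15.4 ± 0.409 to 1.12 ± 0.117 FPKM) and the lysosomal glucosidase GAA (from 25.8 ± 0.30 to 2.73 ± 0.280 FPKM).

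The 37 tested genes of G2 and mitosis were all higher in BxPC3, with a median log2 change of 1.15 and the same count adjusted over the list alone (camera adjusted p = 2.65e-15, and adjusted p = 0.00764 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, rose 4.40-fold, and the mitotic kinases AURKA and PLK1 rose 3.15-fold and 3.29-fold. The 39 tested genes of the G1/S transition were higher too, 39 of them adjusted over the list alone, with a median of 0.78 (camera adjusted p = 6.70e-13, but adjusted p = 0.0735 with an estimated correlation). They included the phosphatase CDC25A (4.08-fold), the licensing factor CDC6 (3.40-fold) and the helicase subunit MCM4 (2.16-fold). Of 26 genes of homologous recombination and Fanconi anaemia repair, 22 rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 5.56e-05, and adjusted p = 0.0863 with an estimated correlation). The list of replication-dependent histones, whose mRNAs mostly lack poly-A tails, also held H1F0, a linker histone expressed outside S phase. Of 11 tested members 8 were higher and 1, H1F0, lower, the same counts adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.279 with an estimated correlation). HIST1H2BJ rose 5.12-fold, while H1F0 fell by 0.71 on the log2 scale.

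Interferon-stimulated genes rose in BxPC3: 32 of 38 were higher and 5 lower, the same counts adjusted over the list alone, with a median log2 change of 1.39 (camera adjusted p = 8.87e-09, and adjusted p = 0.00764 with an estimated correlation). OASL rose 4.74-fold and IFIT1 14-fold. Secreted factors of the senescence-associated phenotype were higher for 26 of 34 members and lower for 7, the same counts adjusted over the list alone (camera adjusted p = 1.16e-05, but adjusted p = 0.208 with an estimated correlation). The chemokine CXCL3 rose 4.60-fold and the cytokine IL1A 2.92-fold. Of NRF2 targets, 19 of 26 were higher and 1 lower, or 20 and 1 adjusted over the list alone (camera adjusted p = 5.06e-05, and adjusted p = 0.305 with an estimated correlation). TXNRD1, thioredoxin reductase, rose 2.67-fold.

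Ribosomal protein genes fell in BxPC3, with 48 of 50 lower and none higher, the same counts adjusted over the list alone, and a median log2 change of -0.88 (camera adjusted p = 2.37e-12, but adjusted p = 0.400 with an estimated correlation). RPL3 fell from 427 ± 25.9 to 173 ± 12.2 FPKM. Mitochondrial ribosomal RNA genes took 0.643% to 0.684% of reads in controls and 0.348% to 0.370% with gemcitabine. A list of MYC targets, most of them nucleolar genes of ribosome assembly, moved the other way: 26 of 29 were higher and none lower, the same counts adjusted over the list alone (camera adjusted p = 4.36e-07, but adjusted p = 0.199 with an estimated correlation). NOP56, a nucleolar protein of ribosome assembly, rose 2.09-fold, and ODC1, a member outside ribosome assembly and the first enzyme of polyamine synthesis, 3.53-fold. Genes of the classical subtype of pancreatic cancer were lower for 11 of 14 members and higher for 2, the same counts adjusted over the list alone (camera adjusted p = 0.00497, but adjusted p = 0.208 with an estimated correlation). AGR2 fell from 134 ± 11.8 to 30.7 ± 2.03 FPKM and CEACAM5 from 242 ± 4.62 to 102 ± 3.54 FPKM, while the mucin MUC13 rose 4.14-fold.

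Targets of p53 went both ways in BxPC3, which carries mutant p53: 12 of 32 were higher and 14 lower, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.877). The cell cycle inhibitor CDKN1A rose 2.01-fold and the exonuclease AEN 3.23-fold. In all, 15 of 36 tested lists passed camera in BxPC3, and 2 of them with an estimated correlation.

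The second comparison asked the same of PANC-1. Genes of mitosis, secreted factors of the senescence-associated phenotype and interferon-stimulated genes rose, and ribosomal protein genes fell. The ribosomal protein call was lost with an estimated correlation (camera adjusted p = 0.0770), and the others held. The collagenase MMP1 rose 12.5-fold (from 8.11 ± 0.162 to 102 ± 6.18 FPKM), the hyaluronan synthase HAS3 10.7-fold and the secreted glycoprotein STC1 8.14-fold. RFLNA, an actin-binding refilin, fell from 9.76 ± 0.714 to 0.966 ± 0.271 FPKM, the co-repressor TLE2 from 7.50 ± 0.393 to 0.770 ± 0.200 FPKM and the guidance factor SEMA3C from 66.5 ± 1.73 to 15.4 ± 2.63 FPKM. The inducible chaperone HSPA6 fell from 9.43 ± 0.548 to 1.39 ± 0.415 FPKM. The cystatin CST1 rose 7.56-fold, but its reads are uncertain because of close paralogs.

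Of 12508 genes tested with limma in PANC-1, 2595 were higher and 3007 lower, and 401 and 133 of them passed an absolute log2 change of 1. Without gemcitabine replicate 1 the counts rose to 4102 higher and 4626 lower, and with the GC trend of each library removed, an alternative chosen after seeing the data, they were 3654 and 4604. Of the 5602 genes called with all 8 libraries, 5569 were also called without that library. In 45.8% of the tested genes the 4 gemcitabine libraries all lay on the same side of the 4 controls, where chance gives 2.86%.

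The 37 tested genes of G2 and mitosis were all higher in PANC-1, with the same count adjusted over the list alone and a median log2 change of 1.56 (camera adjusted p = 8.00e-24, and adjusted p = 0.0450 with an estimated correlation). The mitotic kinesins KIF20A and KIF2C rose 6.21-fold and 3.91-fold, and the ubiquitin-conjugating enzyme UBE2C 3.05-fold. Of 38 G1/S genes, 32 rose and 1 fell, or 35 and 1 adjusted over the list alone (camera adjusted p = 2.60e-13, and adjusted p = 0.0134 with an estimated correlation). The helicase component CDC45 rose 4.10-fold and the ubiquitin ligase adaptor DTL 2.51-fold. Repair genes of homologous recombination were higher for 21 of 27 members and lower for 1, the same counts adjusted over the list alone (camera adjusted p = 1.61e-07, but adjusted p = 0.169 with an estimated correlation). The histone list went both ways, with 3 members higher, H1F0 among them, and 4 lower of 11, the same counts adjusted over the list alone (camera adjusted p = 0.811).

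Interferon-stimulated genes rose in PANC-1 for 23 of 31 members and fell for 3, or 25 and 3 adjusted over the list alone, with a median log2 change of 0.71 (camera adjusted p = 1.99e-07, and adjusted p = 0.0134 with an estimated correlation). OAS3, a synthetase activated by double-stranded RNA, rose 3.73-fold, and the antiviral GTPase MX1 5.90-fold, whereas IFITM1, a membrane protein that restricts virus entry, fell from 154 ± 6.99 to 34.9 ± 2.01 FPKM. Secreted factors of the senescence-associated phenotype rose for 20 of 26 and fell for 3, the same counts adjusted over the list alone (camera adjusted p = 1.21e-08, and adjusted p = 0.0397 with an estimated correlation). The urokinase gene PLAU rose 4.21-fold and the metalloproteinase inhibitor TIMP2 2.74-fold. The 7 tested genes of the 28 listed for the basal-like subtype were all higher, also adjusted over the list alone (camera adjusted p = 4.95e-07, and adjusted p = 0.0403 with an estimated correlation), and the EGFR ligand AREG rose 4.90-fold. The basal-like list did not pass in BxPC3, with 16 of 27 members higher and 7 lower (camera adjusted p = 0.0836). It did not pass for the difference between lines either (camera adjusted p = 0.769). EGFR ligands and MAPK feedback genes were higher for 12 of 21 and lower for 6, or 14 and 6 adjusted over the list alone (camera adjusted p = 0.00756, but adjusted p = 0.0770 with an estimated correlation). Cyclin D1, encoded by CCND1, rose 2.80-fold, and the receptor feedback inhibitor SPRY1 fell from 23.4 ± 0.664 to 9.80 ± 0.252 FPKM.

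Ribosomal protein genes fell in PANC-1 for 42 of 50 members, or 44 adjusted over the list alone, and none rose (median log2 change -0.41, camera adjusted p = 1.30e-11, but adjusted p = 0.0770 with an estimated correlation). RPS20 fell from 152 ± 5.26 to 96.2 ± 2.13 FPKM. Mitochondrial ribosomal RNA genes took 0.270% to 0.280% of reads in controls and 0.106% to 0.169% with gemcitabine. The p53 targets did not pass as a list, with 10 higher and 4 lower of 30, the same counts adjusted over the list alone (camera adjusted p = 0.173). CDKN1A rose 3.04-fold and the BH3-only gene PMAIP1 2.44-fold in this line, which also carries mutant p53. In all, 15 of 36 lists passed camera, and 5 of them with an estimated correlation.

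Some list calls in PANC-1 were lost when gemcitabine replicate 1 was left out. Epithelial genes were higher for 10 of 19 members and lower for 2, the same counts adjusted over the list alone (camera adjusted p = 0.0184, but adjusted p = 0.195 with an estimated correlation and 0.0667 without that library), and the median log2 change was 0.28 with that library and 0.35 without it. YAP targets were higher for 10 of 17 and lower for 3, the same counts adjusted over the list alone (camera adjusted p = 0.0328, but adjusted p = 0.221 with an estimated correlation and 0.108 without that library), and the median was 0.32 with that library and 0.23 without it. Immediate early genes were higher for 10 of 21 and lower for 2, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0130, but adjusted p = 0.306 with an estimated correlation and 0.0853 without that library), and the median was 0.23 with that library and 0.12 without it. Genes of the unfolded protein response were lower for 9 of 23 and higher for 2, the same counts adjusted over the list alone (camera adjusted p = 0.0426, but adjusted p = 0.236 with an estimated correlation and 0.0667 without that library), and the median was -0.15 with that library and -0.20 without it. The unfolded protein response call was also lost without control replicate 1 (adjusted p = 0.0517) and without control replicate 4 (adjusted p = 0.0511). XBP1, a transcription factor of that response, fell from 54.8 ± 1.52 to 36.1 ± 0.800 FPKM, the desmosomal protein DSP rose 3.12-fold, and the immediate early factor KLF4 3.53-fold.

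**Figure D2:**
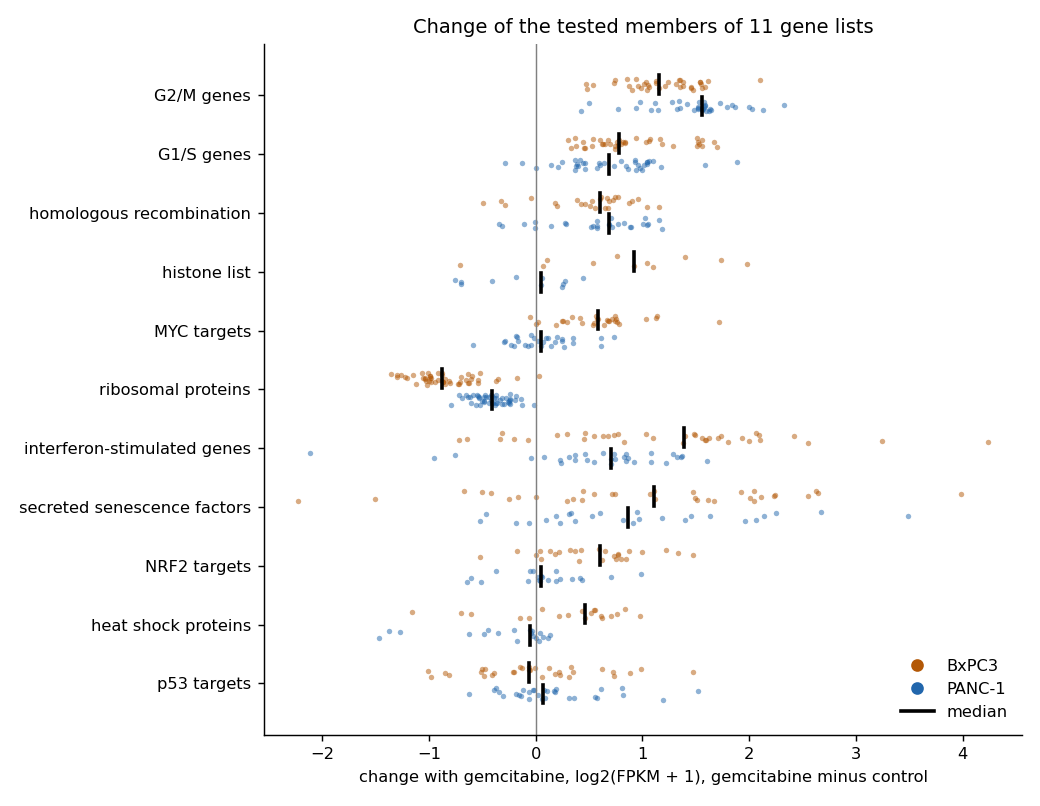
Change with gemcitabine of each tested member (points) of 11 gene lists in BxPC3 (orange) and PANC-1 (blue), in log2(FPKM + 1), gemcitabine minus control, with the list median as a black bar. The G2/M median lies at 1.15 in BxPC3 and 1.56 in PANC-1, and the ribosomal protein median at -0.88 and -0.41.

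Genes of gemcitabine uptake, metabolism and target enzymes were compared in both lines. CDA, the cytidine deaminase that inactivates gemcitabine (ENSG00000158825, chromosome 1, 20588948 to 20618908, GRCh38), rose 4.59-fold in BxPC3 (from 11 ± 0.538 to 50.5 ± 3.71 FPKM; log2 change 2.10 ± 0.06 SE, limma adjusted p = 9.82e-10). In PANC-1 it had 5 reads over the 4 controls and 30 over the 4 gemcitabine libraries and was too low to test. Of ribonucleotide reductase, which gemcitabine diphosphate inhibits, the subunits RRM1 and RRM2 rose in both lines: RRM1 1.82-fold in BxPC3 and 2.21-fold in PANC-1, and RRM2 3.68-fold and 4.73-fold. The p53-inducible subunit RRM2B fell from 3.49 ± 0.0782 to 2.89 ± 0.195 FPKM in BxPC3 (limma adjusted p = 0.00233) and stood at 13.8 ± 0.856 FPKM in control and 11 ± 3.02 FPKM with gemcitabine in PANC-1 (limma adjusted p = 0.163). Thymidylate synthase, encoded by TYMS, rose 1.83-fold and 2.12-fold, and the ecto-nucleotidase NT5E 1.94-fold and 2.76-fold. The equilibrative transporter SLC29A1 rose 2.21-fold in BxPC3 (from 3.55 ± 0.0954 to 7.83 ± 0.484 FPKM) and stood at 62.4 ± 2.11 FPKM in control and 60.7 ± 10.2 FPKM with gemcitabine in PANC-1 (limma adjusted p = 0.721), a difference of -1.01 (log2, PANC-1 minus BxPC3) with limma adjusted p = 2.54e-06. DCK, the kinase that activates gemcitabine, rose 1.18-fold in BxPC3 and had a log2 change of 0.01 ± 0.19 SE in PANC-1 (limma adjusted p = 0.977). Gemcitabine replicate 1 decided these 3 PANC-1 values: without it RRM2B changed by -0.13 (limma adjusted p = 0.0284), SLC29A1 by -0.16 (limma adjusted p = 0.00161) and DCK by 0.22 (limma adjusted p = 0.00667) on the log2 scale. The triphosphohydrolase SAMHD1 rose 3.65-fold in BxPC3 and 1.45-fold in PANC-1, and the CTP synthase CTPS1 3.11-fold and 1.51-fold. The export pump ABCC4 rose 1.58-fold in BxPC3 and fell from 13.2 ± 0.258 to 6.59 ± 0.691 FPKM in PANC-1. Of the list, 18 of 27 members were higher and 5 lower in BxPC3, or 18 and 6 adjusted over the list alone (camera adjusted p = 0.00771, but adjusted p = 0.103 with an estimated correlation). In PANC-1, 11 of 25 were higher and 3 lower, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0624).

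**Figure D3:**
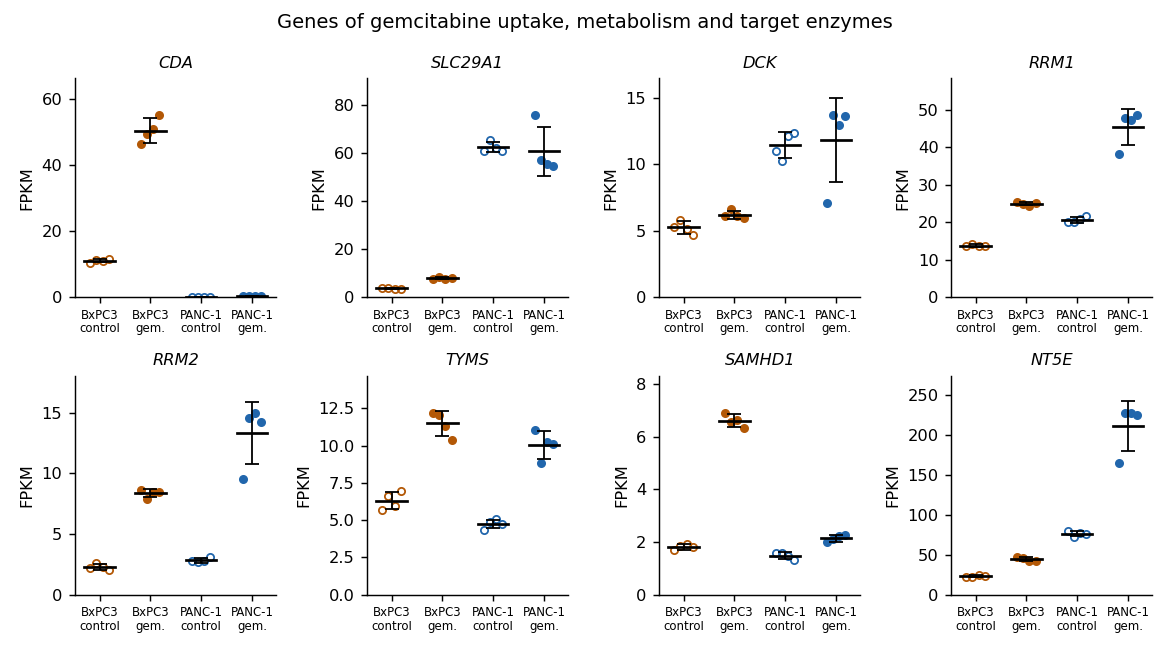
FPKM of 8 genes in each library (points; open for control, filled for gemcitabine; orange BxPC3, blue PANC-1), with the mean as a bar and the SD over 4 libraries as error bars, on linear axes that start at 0. RRM1 and RRM2 are higher with gemcitabine in both lines, and CDA reaches 50.5 FPKM in BxPC3 with gemcitabine and stays under 1 FPKM in PANC-1.

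The third comparison asked whether the effect of gemcitabine differed between the lines. SPP1 fell in BxPC3 and rose 10.6-fold in PANC-1 (from 0.701 ± 0.0939 to 7.44 ± 0.172 FPKM), a difference of 5.56 ± 0.09 SE on the log2 scale (limma adjusted p = 2.96e-16). The netrin NTN4 fell from 44.2 ± 0.533 to 27.6 ± 0.951 FPKM in BxPC3 and rose 6.0-fold in PANC-1, and NDRG1, a gene induced by hypoxia, fell from 17.1 ± 0.218 to 5.95 ± 0.171 FPKM and rose 4.49-fold. CYP1A1, the classic target of the aryl hydrocarbon receptor, rose 23.2-fold in BxPC3 and fell from 2.27 ± 0.180 to 1.06 ± 0.123 FPKM in PANC-1. Other differences came from genes that PANC-1 hardly expressed: SERPINB2, PPBP and SPRR1B rose in BxPC3, and IL33 and CYP4B1 fell there, while PPBP, SPRR1B, IL33 and CYP4B1 had no read in any PANC-1 library and SERPINB2 had 7 reads over its 4 gemcitabine libraries.

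Of 14134 genes tested with limma over the 16 libraries, the effect was above that of BxPC3 in PANC-1 for 3565 and below it for 3754. Without PANC-1 gemcitabine replicate 1 these counts were 4509 and 4685. Of the 7319 genes, 5303 were also tested in each line alone. The interferon-stimulated genes rose less in PANC-1, with 24 of 39 members below BxPC3 and 8 above, the same counts adjusted over the list alone (camera adjusted p = 4.81e-05, and adjusted p = 0.00570 with an estimated correlation). Of the 39 members, 31 were tested in PANC-1 itself, and with limma-voom the camera adjusted p was 0.0345. The interferon list was the only list of the 12 past camera that held with an estimated correlation. Ribosomal protein genes fell less in PANC-1, 38 of 50 members being above BxPC3, or 39 adjusted over the list alone (camera adjusted p = 1.51e-06, but adjusted p = 0.438 with an estimated correlation). MYC targets, mostly of ribosome assembly, were below BxPC3 for 20 of 29 members, also adjusted over the list alone (camera adjusted p = 1.04e-05, but adjusted p = 0.0788 with an estimated correlation). Heat shock genes were below BxPC3 for 15 of 19 members, also adjusted over the list alone (camera adjusted p = 8.31e-05, but adjusted p = 0.106 with an estimated correlation). HSPH1 rose 2.06-fold in BxPC3, and HSPA1A, whose reads are uncertain because HSPA1B is a near-identical copy, fell from 133 ± 5.31 to 47.9 ± 8.23 FPKM in PANC-1. The histone list was below BxPC3 for 10 of 12 members and above it for 1, H1F0, the same counts adjusted over the list alone (camera adjusted p = 0.00201, but adjusted p = 0.113 with an estimated correlation).

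Other lists also differed between the lines. Classical subtype genes were above BxPC3 for 11 of 15 members and below it for 3, the same counts adjusted over the list alone (camera adjusted p = 0.00146, but adjusted p = 0.0788 with an estimated correlation), although only 5 of them were tested in PANC-1 itself. NRF2 targets were below BxPC3 for 15 of 26 and above it for 2, the same counts adjusted over the list alone (camera adjusted p = 0.00714, but adjusted p = 0.356 with an estimated correlation). Genes of G2 and mitosis were above BxPC3 for 20 of 37 and below it for 3, the same counts adjusted over the list alone (camera adjusted p = 0.00750, but adjusted p = 0.438 with an estimated correlation). Unfolded protein response genes were below BxPC3 for 14 of 23 and above it for 4, or 19 and 4 adjusted over the list alone (camera adjusted p = 0.0138, but adjusted p = 0.212 with an estimated correlation). YAP targets were below BxPC3 for 10 of 19 and above it for 3, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0251, but adjusted p = 0.276 with an estimated correlation). Epithelial genes were above BxPC3 for 16 of 34 and below it for 7, or 16 and 8 adjusted over the list alone (camera adjusted p = 0.0139, but adjusted p = 0.282 with an estimated correlation and 0.0577 without PANC-1 gemcitabine replicate 1), and the median difference was 0.23 with that library and 0.15 without it. Only 19 of the 34 epithelial genes were tested in PANC-1 itself. G1/S genes were below BxPC3 for 17 of 39 and above it for 8, or 18 and 8 adjusted over the list alone (camera adjusted p = 0.0372, but adjusted p = 0.282 with an estimated correlation and 0.0869 without PANC-1 gemcitabine replicate 1), and the median difference was -0.25 with that library and -0.20 without it.

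The lines were also compared by the overlap of their calls, over 10670 genes tested in both. The mitotic scaffold ANLN rose 3.25-fold in BxPC3 and 3.32-fold in PANC-1, STC1 8.05-fold and 8.14-fold, and the growth factor binding protein IGFBP6 4.17-fold and 3.51-fold. The adhesion protein BCAM fell from 181 ± 8.64 to 24.7 ± 0.580 FPKM in BxPC3 and from 17.7 ± 0.867 to 4.27 ± 1.15 FPKM in PANC-1, and the transcription factor CREB3L1 from 18.7 ± 0.573 to 5.06 ± 0.266 FPKM and from 11.2 ± 0.467 to 2.40 ± 0.376 FPKM. In both lines 1350 genes were higher, against 845 for independent lists (Fisher's exact test, 2-sided p = 6.74e-132), and 1362 were lower, against 827 (exact p = 1.55e-144). At an adjusted p under 0.05, opposite calls were fewer than independent lists would give: 464 genes were higher in BxPC3 and lower in PANC-1 (against 901), and 440 the reverse (against 775). With an absolute log2 change of 1 also required, neither class passed Fisher's exact test: 4 genes against 2.78 (exact p = 0.361) and 4 against 9.29 (exact p = 0.0879). Fisher's test counts genes as independent units, which they are not, so its p-values do not measure the spread between libraries or cultures. Without PANC-1 gemcitabine replicate 1, 3992 genes were called in the same direction in both lines, against 2712 with it. Across genes, which are not independent replicates, the fold changes of the lines correlated with Spearman's rho of 0.399. No control library was shared between the lines.

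**Figure D4:**
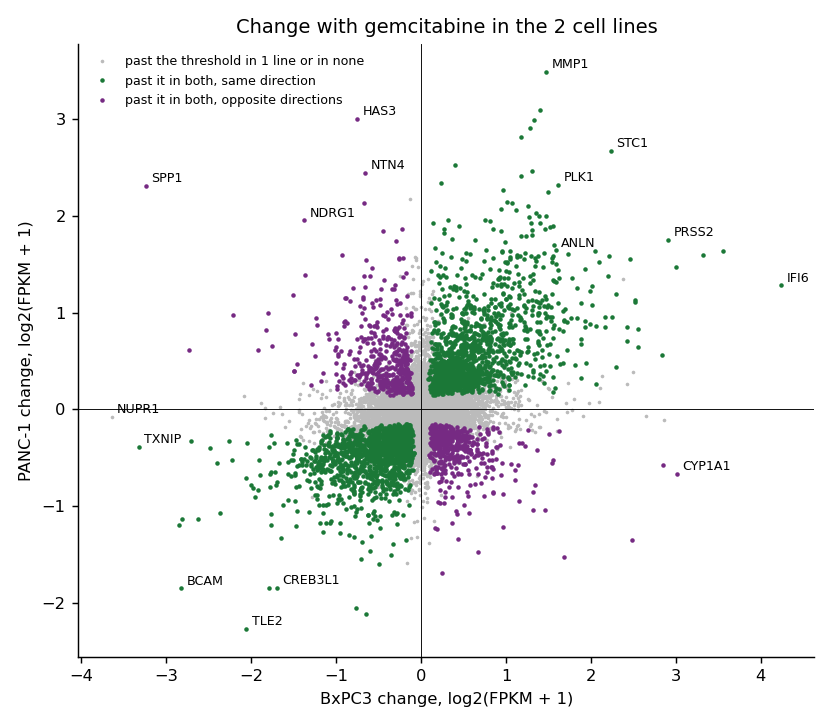
Change with gemcitabine in BxPC3 (x axis) and PANC-1 (y axis), log2(FPKM + 1), for each gene tested in both lines. Green points passed the threshold in both lines in the same direction (1350 higher and 1362 lower), purple points in opposite directions, and grey points in 1 line or in none.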

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

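Of the tests in this part, the exchange of line labels, the depth test of PANC-1 gemcitabine replicate 1, both tests of the scaling of the libraries, the removal of each library's GC trend and limma-voom were chosen only after the result was seen. A chance division of the 8 libraries is an unlikely source of the count of genes called in each line. The real grouping gave 8964 genes in BxPC3, with at most 0 in any other split. In PANC-1 it gave 5602, with at most 1 (1 of 35 splits as large in each line, the real one). Since the libraries may be technical replicates, the splits do not address chance differences between cultures. For the difference between lines, log2 values were centred per line and the line labels exchanged among the libraries of each treatment, which takes equal effects in both lines as its null. The real labels gave 7319 genes and the other splits at most 1 (1 of 100 splits as large, the real one). This argues against a chance division of these libraries, with the same limit about cultures. Relabelling treatment within each line, the test first planned, takes no effect in either line as its null and decides nothing about this difference. An equal fold of a gene that is low in 1 line can also give a difference on the log2(FPKM + 1) scale, and 7061 genes passed with a pseudocount of 0.1.

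The first pattern is PANC-1 gemcitabine replicate 1, which stood apart on the second principal component and lay at the edge of its group for 29 of the named genes. Genes with no read in PANC-1 controls and at least 20 FPKM in BxPC3 reached 0.0499% of their BxPC3 level there, which argues against BxPC3 cells in the library. The effect of the other 3 libraries took 7.16% of the variance of the deviation, which argues against a diluted response as the main cause. The slope on that effect was -0.224, and a partly diluted response stays open, since the test was not repeated with the GC trend removed. Counting noise does not account for the deviation, with chi-square per degree of freedom of at least 55.6 against each of the other 3. GC content, gene length and level together took 72.7% of the variance, GC content alone 72.6%, and removing the GC trend lowered the SD of the deviation from 0.394 to 0.206 log2. A difference in library preparation or amplification is thus a candidate explanation for most of the deviation, and no biological explanation was tested, since the design names none within a group.

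The second pattern is the fall of ribosomal protein genes in both lines, where the list calls were lost with an estimated correlation (adjusted p = 0.400 in BxPC3 and 0.0770 in PANC-1). After removal of the trend with length, GC content and level the list median nearer 0 was -0.40, and under the other scalings -0.38, which argues against these as the whole cause. Reads did not move to processed pseudogenes, which fell too: their reads changed by -3.27% of the reads the parent genes lost, in the line with the higher value, while the 84 genes went from 77510 to 40320 CPM (recovered reads) in BxPC3 and from 53700 to 39360 in PANC-1. A median of -0.24 for other mRNAs with a 5' terminal oligopyrimidine tract, some of them parts of the ribosome, in the line nearer 0, is in line with a fall of that class of mRNAs under gemcitabine, but in BxPC3 the list was lost with an estimated correlation (camera p = 0.168). Poly-A selection stays open, since no tail length was measured here and reads of mitochondrial ribosomal RNA, whose tails are short, took a lower share in every gemcitabine library of each line (0.348% to 0.370% against 0.643% to 0.684% in BxPC3, and 0.106% to 0.169% against 0.270% to 0.280% in PANC-1), which either selection or the level of that RNA could give.

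The third pattern is the rise of G1/S and G2/M genes in both lines, although gemcitabine blocks DNA synthesis, and the G1/S call in BxPC3 was lost with an estimated correlation (adjusted p = 0.0735). The lowest median over both lists and lines was 0.68 after removal of the trend with length, GC content and level and 0.71 under the other scalings, which argues against both. An increased share of cells held in S or G2 phase may account for it, as a hypothesis that was not tested, since bulk levels do not give the phase of single cells.

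The effect of gemcitabine differed between the lines for 12 lists by camera on the interaction and for some genes by limma. With an estimated correlation the difference held for interferon-stimulated genes (camera adjusted p = 0.00570) and was lost for the other lists, with adjusted p from 0.0788 to 0.438. The median difference on the log2 scale, PANC-1 minus BxPC3, was 1.02 for classical subtype genes, 0.47 for ribosomal protein genes, 0.38 for genes of G2 and mitosis and 0.23 for epithelial genes (0.15 without PANC-1 gemcitabine replicate 1). It was -0.87 for the histone list, -0.58 for heat shock genes, -0.52 for interferon-stimulated genes, -0.51 for the MYC targets, -0.47 for YAP targets, -0.40 for NRF2 targets, -0.31 for the unfolded protein response and -0.25 for G1/S genes. Of the named genes, 50 differed by at least 1 on the log2 scale. Above BxPC3, the difference was 5.56 for SPP1, 3.80 for CP, 3.76 for HAS3, 3.56 for NUPR1, 3.33 for NDRG1, 3.11 for NTN4, 2.95 for IL33 and 2.94 for TXNIP. Smaller differences above it were 2.80 for CYP4B1, 2.22 for AGR2, 2.01 for MMP1, 1.66 for GAA, 1.64 for CST1, 1.56 for KDR, 1.5 for CCND1 and 1.34 for CEACAM5, and then 1.32 for DSP, 1.21 for AREG, 1.17 for COL3A1, 1.16 for H1F0, 1.08 for KLF4 and 1.07 for KIF20A. Below BxPC3, the difference was -4.99 for SPRR2E, -4.11 for PPBP, -3.95 for SERPINB2, -3.68 for CYP1A1, -3.49 for SPRR2A, -3.47 for CXCL5, -2.98 for IFI27, -2.95 for IFI6 and -2.54 for RFLNA. It was -2.25 for HSPA6, -2.14 for SPRR1B, -2.06 for CDH5, -2.01 for OASL, -1.92 for HIST1H2BJ, -1.81 for CXCL3, -1.80 for CDA, -1.73 for IFIT1 and -1.47 for F3, and it was -1.46 for IFITM1, -1.40 for TXNRD1, -1.34 for IL1A, -1.33 for MUC13, -1.29 for SEMA3C, -1.26 for ABCC4, -1.18 for MICB, -1.11 for ODC1, -1.09 for SAMHD1 and -1.01 for SLC29A1. Of these, the differences of CDA and IL1A turned to 0.00480 and 1.27 with limma-voom on the recovered reads, the call of MUC13 was lost with limma-voom and that of IL1A with a pseudocount of 0.1. Some of the listed genes were hardly expressed in 1 line. PPBP, SPRR1B, IL33 and CYP4B1 had no read in PANC-1, and SERPINB2 had few. CDA, CDH5 and COL3A1 were too low to test in PANC-1, and KDR in BxPC3. For these genes the difference mainly gives the change in the other line and does not show a weaker or opposite response. They are examples, and other listed genes, such as SPRR2E, MUC13 and IL1A, may also have been low in PANC-1. For SPRR2E the rise in BxPC3 gives nearly the whole difference of -4.99. A listed difference alone therefore does not show that both lines responded.

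A library lay apart from the other 3 of its group, by the gap to its nearest neighbour over the range of the group, in 54 of 399 groups of 4 values examined, where chance gives about 1 in 20. PANC-1 gemcitabine replicate 1 accounted for 29 of them. The 25 others are close to the number that chance gives over 399 groups, so single entries among them may be chance. PANC-1 gemcitabine replicate 1 was the highest, with this ratio in parentheses, for BCAM (0.836), BCL2L1 (0.914), CD14 (0.915), CDC20 (0.882), COL1A1 (0.916), ESAM (0.839), GAA (0.914), HSPA1A (0.856), HSPA1B (0.938), IFI6 (0.928), LIF (0.914), RPL3 (0.899) and SLC29A1 (0.883). It was the lowest for ANLN (0.974), AURKA (0.875), CDC6 (0.870), DCK (0.882), HMGCS1 (0.979), HSPH1 (0.890), IFIT1 (0.914), NT5E (0.957), RRM1 (0.865), RRM2 (0.855), RRM2B (0.884), SEMA3C (0.837), SMAD4 (0.923), SQLE (0.903), STC1 (0.851) and TXNRD1 (0.911). Elsewhere in PANC-1 the ratio stood out in controls for HNRNPA1L2 (replicate 4 highest, 0.926), MUC13 (replicate 2 lowest, 0.924), OAS3 (replicate 3 lowest, 0.864), ODC1 (replicate 4 highest, 0.868), RPL3 (replicate 1 lowest, 0.864), RRM2 (replicate 4 highest, 0.833) and TLE2 (replicate 2 highest, 0.863) and in the gemcitabine group for CDH5 (replicate 2 highest, 1.0) and KIF2C (replicate 4 lowest, 0.858). In BxPC3 it stood out in controls for AGR2 (replicate 2 highest, 0.882), BCL2L1 (replicate 2 highest, 0.838), DSP (replicate 2 lowest, 0.938), HMGCS1 (replicate 3 highest, 0.908), KDR (replicate 2 highest, 1.0), KIF2C (replicate 3 lowest, 0.898), NUPR1 (replicate 2 highest, 0.831), OAS3 (replicate 2 lowest, 0.859), PLAU (replicate 2 highest, 0.874), RRM1 (replicate 2 highest, 0.892), TXNIP (replicate 2 highest, 0.991) and UBE2C (replicate 2 highest, 0.854). BxPC3 control replicate 2 also differed as a library. Its chi-square per degree of freedom was 14.3 to 16.9 against the other controls, which gave 2.07 to 2.79 among themselves. Without it 9117 genes were called in BxPC3, against 8964 with it. In the gemcitabine group of BxPC3 the ratio stood out for KDR (replicate 3 highest, 1.0), NOP56 (replicate 4 highest, 0.964), PLAU (replicate 4 highest, 0.831) and SPRY1 (replicate 3 lowest, 0.936). A ratio of 1.0 came from genes with equal values in the other 3 libraries of the group.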

How the results depend on the processing

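Of the alternatives here, limma-voom on the recovered reads and the removal of each library's GC trend were chosen only after the data were seen. The 3 counts of genes stayed within 1.5 times their value under another pseudocount, no filter, median-ratio scaling, TPM rescaling, limma without trend and robust, protein-coding genes only, the replicate block and limma-voom. The split by direction was less even with TPM rescaling. In BxPC3 5199 genes were then higher and 3687 lower, against 4556 and 4408. For the difference 42.6% of calls were then above BxPC3, against 48.7%. Leaving out each library in turn gave 8543 to 9117 genes in BxPC3, 4641 to 8728 in PANC-1 (2189 to 4102 higher, 2452 to 4626 lower) and 6868 to 9194 for the difference between lines, and each highest PANC-1 value came without PANC-1 gemcitabine replicate 1. With the GC trend removed, 8258 genes were called in PANC-1, 4604 of them lower, and 98.9% of the genes called in the deposited values were among them. Requiring an absolute log2 change of 1 left 1029 genes in BxPC3 (538 higher, 491 lower), 534 in PANC-1 (401 higher, 133 lower), 1093 for the difference (647 above, 446 below) and 150 called in the same direction in both lines, by the stricter criterion itself. In the difference test, 76 called genes had the opposite sign with a pseudocount of 0.1, 16 with TPM rescaling and 228 with limma-voom, of which 17, 4 and 63 passed the threshold both ways. In the tests of single lines 1 called gene in BxPC3 did so, with TPM rescaling. Among the named genes the difference between lines turned from -1.80 to 0.00480 for CDA and from -1.34 to 1.27 for IL1A with limma-voom. CDA reached at most 0.0843 FPKM in a PANC-1 control and 0.407 FPKM with gemcitabine. At such levels the log2(FPKM + 1) scale understates a change, so the -1.80 does not show a weaker response of CDA in PANC-1. The call of IL1A was also lost with a pseudocount of 0.1, as a low level in PANC-1 would give. Its -1.34 thus does not show a weaker response in PANC-1 either.

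Of the gene lists past camera, 2 in BxPC3, 5 in PANC-1 and 1 for the difference passed with an estimated correlation. Fry, which asks only whether a list's genes move 1 way on balance, passed 34, 29 and 31 lists. Without a filter on low values 25 lists passed in PANC-1, with more genes tested. The G1/S list for the difference was also lost with protein-coding genes only (camera adjusted p = 0.0563) and with the GC trend removed (adjusted p = 0.0614), where its median was -0.25 and -0.26, against -0.25 with all genes and no removal, so the difference was as large and the cause of the lost calls was not tested. Over its alternatives the camera adjusted p ran from 2.41e-04 without a filter to 0.282 with an estimated correlation. The replicate numbers did not pair the libraries: same-numbered control and gemcitabine libraries had correlations of their deviations from -0.376 to 0.189, and 0 of 8 libraries in BxPC3 and 2 of 8 in PANC-1 correlated best with their own number. With the replicate block 8553, 4639 and 6608 genes were called, and the unfolded protein response list was lost in PANC-1 (camera adjusted p = 0.0547, and for camera from 4.90e-04 without a filter to 0.236 with an estimated correlation over its alternatives, median-ratio scaling also ending the call). Among named genes in the single lines, calls of COL1A1 and NOP56 in PANC-1 were lost under at least 1 alternative, COL1A1 without single libraries or without the filter and NOP56 with the block. Calls of AGR2, DCK, HSPH1, MICB, NUPR1, RRM2B, SLC29A1 and SQLE in PANC-1 were gained without gemcitabine replicate 1, AGR2, RRM2B and TXNRD1 with the GC trend removed, PSMB9 in BxPC3 with TPM rescaling, the block or without control replicate 2, and HNRNPA1L2 in BxPC3 with protein-coding genes only, the block, the GC trend removed or without control replicate 2 or gemcitabine replicate 4. For the difference between lines, calls were lost for STC1 with a pseudocount of 0.1, TPM rescaling or limma-voom, MX1 with that pseudocount or limma-voom, IL1A with that pseudocount, MUC13 and PDCD1LG2 with limma-voom, RRM1 with TPM rescaling and AURKA with the block. Those of RRM2 and XBP1 were lost without most single libraries, without the filter, and with TPM rescaling, limma-voom or the block, RRM2 also with the other pseudocount and XBP1 with the GC trend removed. Calls were gained for CREB3L1 and TLE2 with the other pseudocount, TPM rescaling, limma-voom, the GC trend removed or without PANC-1 gemcitabine replicate 1, for IGFBP6 with the GC trend removed, and for IGFBP6, ANLN, DTL and HNRNPA1L2 without single libraries. Depth limits the genes with few reads: a change of a gene with under 3 reads in each library was not detectable. The main tests set a higher limit, FPKM of at least 1 in at least 4 libraries, which on a transcript of 1 kb is far above 3 reads. Changes of genes below that limit were not tested there.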

Other observations

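The tests in this part were set before their results were seen, and the removal of each library's GC trend that 1 of them uses was added as a processing step after the data had been seen. Further gene groups moved in BxPC3. Genes of cholesterol synthesis were higher for 16 of 25 members and lower for 4, the same counts adjusted over the list alone (camera adjusted p = 0.0286, but adjusted p = 0.208 with an estimated correlation). HMGCS1, an early enzyme of that pathway, rose 2.63-fold and SQLE, squalene epoxidase, 1.93-fold. Ligands of natural killer and T cell receptors were higher for 13 of 21 and lower for 2, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00985, but adjusted p = 0.109 with an estimated correlation). The stress ligand MICB rose 2.91-fold and the checkpoint ligand PDCD1LG2 8.72-fold. YAP targets were higher for 15 of 18 and lower for 1, the same counts adjusted over the list alone (camera adjusted p = 1.71e-04, but adjusted p = 0.143 with an estimated correlation), and F3, which encodes tissue factor, rose 3.63-fold. Heat shock genes were higher for 13 of 19 and lower for 4, the same counts adjusted over the list alone (camera adjusted p = 0.0347, but adjusted p = 0.455 with an estimated correlation).

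In PANC-1, apoptosis regulators were higher for 11 of 25 members and lower for 2, the same counts adjusted over the list alone (camera adjusted p = 0.0184, but adjusted p = 0.195 with an estimated correlation). The inflammatory caspase CASP4 rose 1.86-fold, and so did the survival gene BCL2L1 (1.48-fold). Targets of NF-kB were higher for 14 of 22 and lower for 2, or 16 and 2 adjusted over the list alone (camera adjusted p = 4.92e-04, but adjusted p = 0.169 with an estimated correlation), and the cytokine LIF rose 2.41-fold. Genes of class I antigen presentation were higher for 8 of 16 and lower for 1, the same counts adjusted over the list alone (camera adjusted p = 0.00920, but adjusted p = 0.165 with an estimated correlation). The immunoproteasome subunit PSMB9 rose 2.50-fold. Oxidative phosphorylation genes passed in neither line, with camera adjusted p = 0.505 in BxPC3 and 0.469 in PANC-1. Few markers of other cell types were tested: COL1A1 and COL3A1 of fibroblasts in BxPC3, COL1A1 and THY1 in PANC-1, CDH5, ESAM and KDR of endothelium, and CD14 of monocytes. CDH5 rose from 0.603 ± 0.0524 to 5.76 ± 0.263 FPKM in BxPC3, and KDR from 0.515 ± 0.112 to 3.47 ± 0.305 FPKM and CD14 from 1.06 ± 0.161 to 2.65 ± 0.776 FPKM in PANC-1. Of the fibroblast markers, 1 was higher and 1 lower in BxPC3, and the 2 tested in PANC-1 were lower (log2 change -0.55 and -0.41). CD14 did not pass in BxPC3 (log2 change 0.04).

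The first hypothesis was that the fall of ribosomal protein genes extends to other mRNAs that begin with a 5' terminal oligopyrimidine tract, a class whose translation and stability are regulated together. A list of 25 such mRNAs outside the ribosomal protein list was fixed before any of their values had been seen. Of 24 tested, 21 were lower and 1 higher in BxPC3 (median log2 change -0.58, camera p = 2.59e-06, and p = 0.168 with an estimated correlation), and 13 were lower and none higher in PANC-1 (median -0.24, camera p = 3.96e-05, and p = 0.0168 with an estimated correlation). Some members of the list, such as FAU and RACK1, are themselves ribosomal proteins or parts of the ribosome, so the list does not stand fully apart from the pattern. A lower level of this mRNA class may thus be part of the pattern, as a hypothesis, and these data do not tell transcription from stability.

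The second hypothesis was that neighbouring genes change together. The fold changes of adjacent tested genes correlated with Spearman's rho of 0.117 in BxPC3 and 0.212 in PANC-1, across genes, which are not independent replicates. The highest of 1000 shuffles of gene order within chromosomes reached 0.0297 and 0.0646. With the GC trend of each library removed the correlations were 0.118 and 0.212, which argues against a shared GC content. Over adjacent genes at least 10000 bases apart they were 0.0848 and 0.190, so reads shared between overlapping genes may account for part of it and cannot be told apart from position in BxPC3, since the value lies between the bounds set beforehand. A regional component of the response remains a hypothesis.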
